A study of Rattus norvegicus with 12 samples.

How the data were processed

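Gene expression was measured with Affymetrix Rat Genome 230 2.0 arrays in primary retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve. Per the labels' protocols, the cells were panned with an antibody to Thy-1.1, a surface protein of RGCs, from Sprague-Dawley rat pups on postnatal days 4 to 6. They were cultured for 7 days in serum-free medium with brain-derived neurotrophic factor, ciliary neurotrophic factor and forskolin, and kept overnight without the neurotrophic factors. They then received 100 nM endothelin-1 (ET-1), endothelin-2 (ET-2) or endothelin-3 (ET-3) for 24 h. The control group is called untreated in the labels' titles and protocol and vehicle-treated in their descriptions, and it is called untreated here. Each of the 4 groups had 3 arrays, numbered 1 to 3 as biological replicates in the labels, which makes 12 arrays.

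The deposited table holds 1 intensity per probe set and array, for 31042 probe sets. The submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probes of a probe set; its version and settings are not given in the sources used here. The deposited intensities are positive, skewed and on a linear scale. The mean after trimming 2% of the values at each end lay between 496.7 and 498.3 on the 12 arrays, so the authors' values appear to have been scaled to a common trimmed mean. Such scaling leaves the rest of each array's distribution as it was: array medians ran from 136 to 181. Detection calls, which state whether a probe set lies above background, were not used here. Probe sets of the platform's control transcripts were not in the table analysed, so the planned 3'/5' values of RNA quality were not computed. For arrays, the number of arrays sets the precision.

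Probe sets were named from the platform annotation supplied with the series. Of the 31042 probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none, and only those with 1 symbol were named. The annotation was set against the RefSeq gene table by Entrez ID, which held 20758 of the single-symbol probe sets, lacked 68 and changed no symbol. A gene with several kept probe sets was represented by the one with the highest mean log2 signal.

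The signal was taken as log2 with no further normalization and no pseudocount. The 15521 probe sets whose mean log2 signal lay at or above the median of all probe sets (a signal of about 147.5) were tested, and they covered 9425 genes. The design fixed before the data were examined was limma (version 3.58.1 in R 4.3.3): lmFit with 4 group means over all 12 arrays, contrasts.fit, and eBayes with an intensity trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 15521 probe sets, with a threshold of 0.05. The contrasts were each endothelin against untreated, the mean of the 3 endothelins against untreated, and each pair of endothelins. This fit has no term for the replicate number and is called the unpaired fit.

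The replicate numbers were then checked. Deviations from the group means correlated between all 18 pairs of arrays that share a number (r from 0.684 to 0.912) and were negatively correlated between arrays of different numbers (r from -0.706 to -0.056 between groups and from -0.758 to -0.232 within a group, across probe sets). Each of the 12 arrays had its best partner in other groups under its own number. Of the variance of the first principal component, 97.9% lay between replicate numbers. All 18 correlations lay over 0.1, the value above which the numbers were taken to pair the arrays. The labels do not say what a replicate number stands for, so the pairing rests on the values. The fit with the replicate number as a block, chosen before the data were examined and called the paired fit, is given beside each comparison. The block lowered the median residual SD from 0.25 to 0.127 on the log2 scale and the residual degrees of freedom from 8 to 6. Fold changes are the same in both fits.

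Genes were named by a rule fixed before the data were examined. It took, per comparison with untreated, the 8 higher and 8 lower genes with the largest change among those past the threshold and with no overlap between the 3 treated and 3 untreated arrays. Open places were filled by unadjusted p among genes changed at least 1.5-fold. For the other contrasts the rule took 6 in each direction. Up to 3 members of each gene list, with the smallest unadjusted p, and the endothelin system genes were added. Because the unpaired fit called nothing, all its places were filled by unadjusted p. The same rule was therefore also read in the paired fit, with the same direction under all 3 replicate numbers in place of separate arrays. That reading was chosen after the data were seen, as were other members of the lists named below.

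Before the data were examined, 32 gene lists were fixed: 21 of pathways or functions and 11 of cell types. Of their 852 entries, 770 matched a named probe set. The 25 lists with at least 5 measured genes were tested with camera in limma, which compares the genes of a list with all other genes. The preset inter-gene correlation was 0.01, adjustment was over the 25 lists, and the test was repeated with an estimated correlation. The lists for the endothelin system, photoreceptors, bipolar cells, oligodendrocytes, retinal pigment epithelium, vascular endothelium and red blood cells had fewer than 5 measured genes and were not tested.

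The fits were tested on simulated data with 50 changed probe sets of each size among the 15521. For ET-1 against untreated, the unpaired fit recovered 58% of changes of 1 on the log2 scale and 92% of changes of 2, and the paired fit 92% and 100%. False calls numbered 0 and 7. Each simulated change was equal under all 3 replicate numbers and set on random probe sets. The measured responses differed between numbers, and the unpaired fit called 0 for ET-1. The recovered shares therefore need not hold for the data. Both lists that were shifted in the simulation were called by camera, and no other list. P-values of comparisons with fewer than 10 arrays per group come from limma. Responses of different endothelins share the untreated arrays, so their correlation was set beside 100 simulated data sets without any effect. Alternatives were other normalizations, a pseudocount of 38.2 (25% of the median signal), other filters, array weights, no intensity trend, the 2 compared groups alone, and each array left out in turn. Repeats of these inside the paired fit, a random replicate block, and leaving out all arrays of a replicate number were added after the data were seen. List medians under quantile normalization and median centring were also computed after the data were seen. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.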

Results

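Expression was profiled in cultured rat RGCs after 24 h with 100 nM ET-1, ET-2 or ET-3, vasoactive peptides that signal through the endothelin A and B receptors, or without peptide. The series addressed which genes respond to each endothelin in these cells. There were 3 arrays per group, each a biological replicate by its label. Median MAS5 signal per array ran from 136 to 181, and the trimmed mean from 496.7 to 498.3.

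The arrays grouped by replicate number before they grouped by treatment. Fibroblast transcripts stood out in the untreated array of replicate 1. Col1a1, the alpha-1 chain of type I collagen, had a signal of 7660 there against 1438 and 1004 in replicates 2 and 3. Lum (lumican) read 7101 against 1106 and 1469, and Dcn (decorin) 6467 against 1293 and 1035. Agtr2, the angiotensin II type 2 receptor, read 5511 against 99.8 and 70.3. The RGC marker Sncg (gamma-synuclein) ran the other way, at 15350 against 22770 and 26260, and Rbpms at 5281 against 8213 and 6327. The first principal component held 56.6% of the variance, and 97.9% of its variance lay between replicate numbers.

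**Figure D1:**
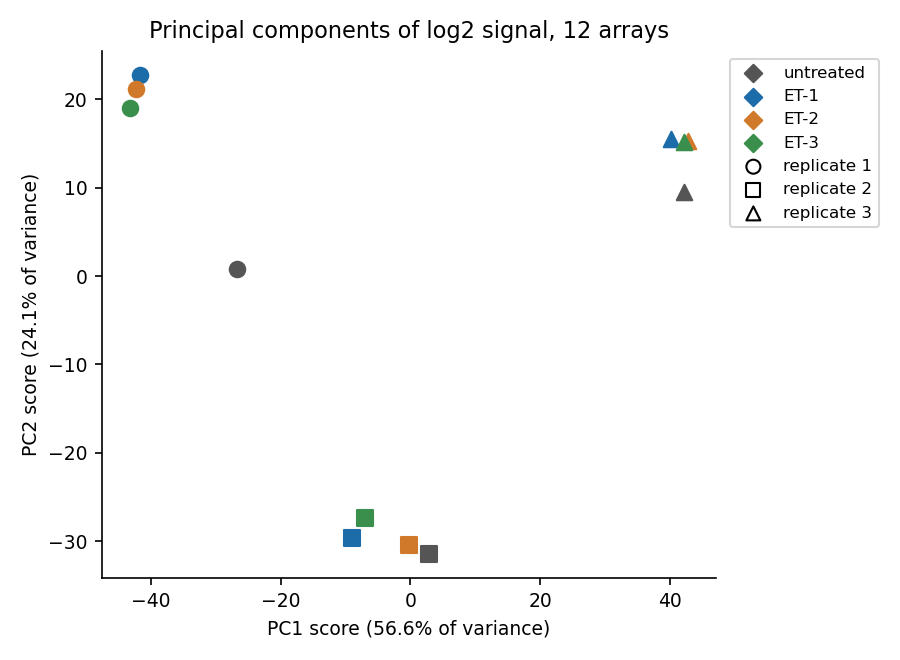
Scores of the 12 arrays on the first 2 principal components of log2 signal over the kept probe sets; colour gives the group and marker shape the replicate number. Arrays with one replicate number stand together, and PC1 and PC2 hold 56.6% and 24.1% of the variance.

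**Figure D2:**
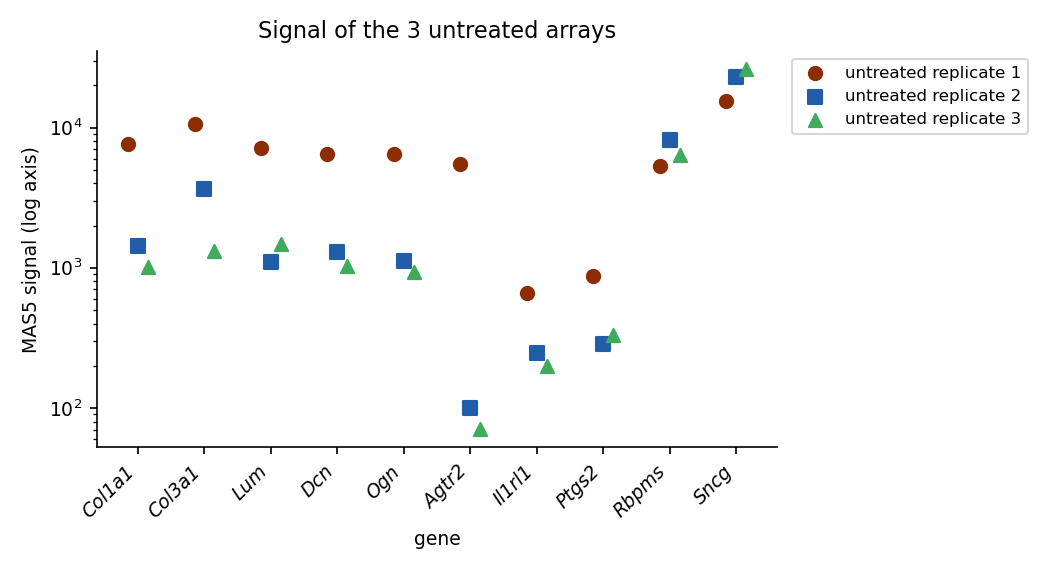
MAS5 signal (log axis) of 10 genes in each of the 3 untreated arrays; marker shape and colour give the replicate. Col1a1, Col3a1, Lum, Dcn, Ogn and Agtr2 are highest in replicate 1 (Agtr2 5511 against 99.8 and 70.3), and Sncg and Rbpms are lowest there.

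ET-1 against untreated asked which genes respond to ET-1. The largest increases were in Il1rl1, the receptor of interleukin-33, whose log2 signal rose by 3.45 ± 0.31 (SE, n = 3 pairs of arrays; 10.9-fold), and Esm1, an endothelial proteoglycan (3.13 ± 0.25). Both cyclooxygenase genes rose, Ptgs1 by 2.19 and Ptgs2 by 1.64 on the log2 scale. So did S100a6, a calcium-binding protein (2.08 ± 0.18), the activin antagonist Fst (1.70), Hrct1 (1.58) and F3, the tissue factor that starts coagulation (1.51). Decreases were seen in Inmt, an N-methyltransferase (-1.69 ± 0.25), Thbd, the anticoagulant receptor thrombomodulin (-1.26 ± 0.12), Crym (-1.10 ± 0.11), Cldn11 (-1.07), Ube3al1 (-0.94), Ogn (-0.83), Eomes (-0.39) and Dlg5 (-0.35). The rule as read in the paired fit had required one direction under all 3 replicate numbers. Limma's adjusted p in that fit ran from 0.00022 (Esm1) to 0.046 (Dlg5).

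Matrix and TGF-beta target genes held the most called genes of the lists with ET-1. In the paired fit 12 of the 36 measured members rose and none fell (limma; 21 and 1 when adjusted over the list alone). They included the matricellular genes Ccn1 (1.45) and Ccn2 (0.81 ± 0.08), the basement membrane collagen Col4a1 (0.85), the protease inhibitor Timp1 (1.05), Tgfb3 (0.97) and the contractile genes Acta2 (0.55) and Tagln (0.76). In the unpaired fit the list shifted upward against other genes (camera adjusted p = 5.2e-11, and 0.274 with an estimated correlation). Of 31 cell cycle genes, Ccnb2 (1.15), Ccnd1 (0.84) and Mcm3 (0.80) rose in the paired fit (19 when adjusted over the list alone), and 30 of the 31 fold changes were positive, with a median of 0.75 (camera adjusted p = 4.9e-08; adjusted p = 0.459 with an estimated correlation). Of 2 other probe sets of Ccnd1, 1 passed (1.28) and 1 did not (0.66). Of 27 inflammatory and NF-kB genes 4 rose: the chemokines Ccl2 (1.33) and Ccl7 (1.33), the adhesion molecule Icam1 (0.86) and Ptgs2, and 11 passed when adjusted over the list alone (camera adjusted p = 3.7e-05; adjusted p = 0.459 with an estimated correlation). Egr1 (0.80) and Ier3 (0.83) rose among 18 immediate early genes, 6 when adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.274 with an estimated correlation).

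Smaller upward shifts with ET-1 were seen in ER stress genes (camera adjusted p = 0.0124), heat shock proteins (0.0371) and cholesterol biosynthesis (0.00544); with an estimated correlation their adjusted p was 0.459, 0.459 and 0.608. Pdia6 rose by 0.28 among 28 ER stress genes, Cryab (0.98) and Hspb1 (0.88) among 17 heat shock genes, and Msmo1 (0.56) among 22 genes of cholesterol synthesis. Nqo1, a quinone reductase, rose by 0.72 and Adm, adrenomedullin, by 0.91. Calcium signalling, ion channel and synaptic vesicle genes shifted downward by small amounts. The median log2 change was -0.10 over 32 calcium signalling genes (camera adjusted p = 0.0122), -0.11 over 23 sodium and potassium channels (0.0158) and -0.08 over 25 genes of synaptic vesicle release (0.0211), and the adjusted p with an estimated correlation was 0.459, 0.459 and 0.608. One member of each fell in the paired fit: Plcg1 (-0.35), Kcna2 (-0.33) and Bsn, the presynaptic scaffold bassoon (-0.30). The pro-apoptotic Bcl2l11 fell by 0.32 and was the single call among 21 apoptosis genes.

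Of the 24 measured RGC markers, 1 fell with ET-1, the transcription factor Eomes (-0.39 ± 0.09, adjusted p = 0.0419 by limma in the paired fit; a second probe set gave -0.38 with adjusted p = 0.258). The median of the RGC list was -0.03 (camera adjusted p = 0.249 unpaired and 0.0288 paired, and adjusted p = 0.321 in the paired fit with an estimated correlation). Of the 8 astrocyte and Müller glia markers Vim (0.69 ± 0.06), Gja1 (1.06) and Clu (0.24) rose, while the median of the list was 0.06 (camera adjusted p = 0.0617 unpaired and 0.00344 paired, and adjusted p = 0.233 in the paired fit with an estimated correlation). The pericyte, smooth muscle and fibroblast list shifted upward (camera adjusted p = 0.0156; adjusted p = 0.274 with an estimated correlation) with a median of 0.13 over 9 genes, of which Acta2 and Tagln rose. Pdgfrb, a pericyte receptor, was at 0.94 ± 0.24 and missed the threshold (adjusted p = 0.0742 by limma in the paired fit).

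The camera calls of the unpaired fit with ET-1 went from 11 lists to 3 without ET-1 replicate 1 and 5 without untreated replicate 2. Leaving out an array in that fit unbalances the replicate numbers. In all, 268 of 15521 probe sets passed in the paired fit with ET-1, 234 higher and 34 lower (182 and 22 genes), and 58 of the higher and 5 of the lower changed at least 2-fold. The unpaired fit called 0 (limma; 237 probe sets had an unadjusted p under 0.05 against 776 expected by chance, and the lowest adjusted p was 0.9999). The genes its rule named, with none past the threshold there, were Myof, a membrane repair protein (1.15 ± 0.18, SE of the unpaired fit), Ccn2, Nthl1 (0.77), Cd9 (0.69), Vamp5 (0.80), Vim, Tnfaip2 (0.80) and S100a11 (0.76) on the higher side. On the lower side they were Inmt, Thbd, Ube3al1, Cldn11, Rap2a (-0.83), Crym, Ccdc30 (-0.60) and Iqub (-0.71). Rap2a, Ccdc30 and Iqub also missed the threshold in the paired fit. The paired count fell to 78 with the 2 groups alone, to 95 without replicate 1 and 23 without replicate 2; without single arrays it was 114 (ET-1 replicate 1), 73 (ET-1 replicate 2), 144 (ET-1 replicate 3), 171 (untreated replicate 1) and 575 (untreated replicate 3). Of the 50 named genes called here, 9 kept their call in all 12 alternatives of the paired fit that left out arrays or replicates, rescaled the signal or added a pseudocount (Ccn2, Crym, Esm1, Gja1, Il1rl1, Myof, S100a6, Thbd and Vim), and the other 41 lost it in at least 1, most often without replicate 2, with an adjusted p of up to 0.419.

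**Figure D3:**
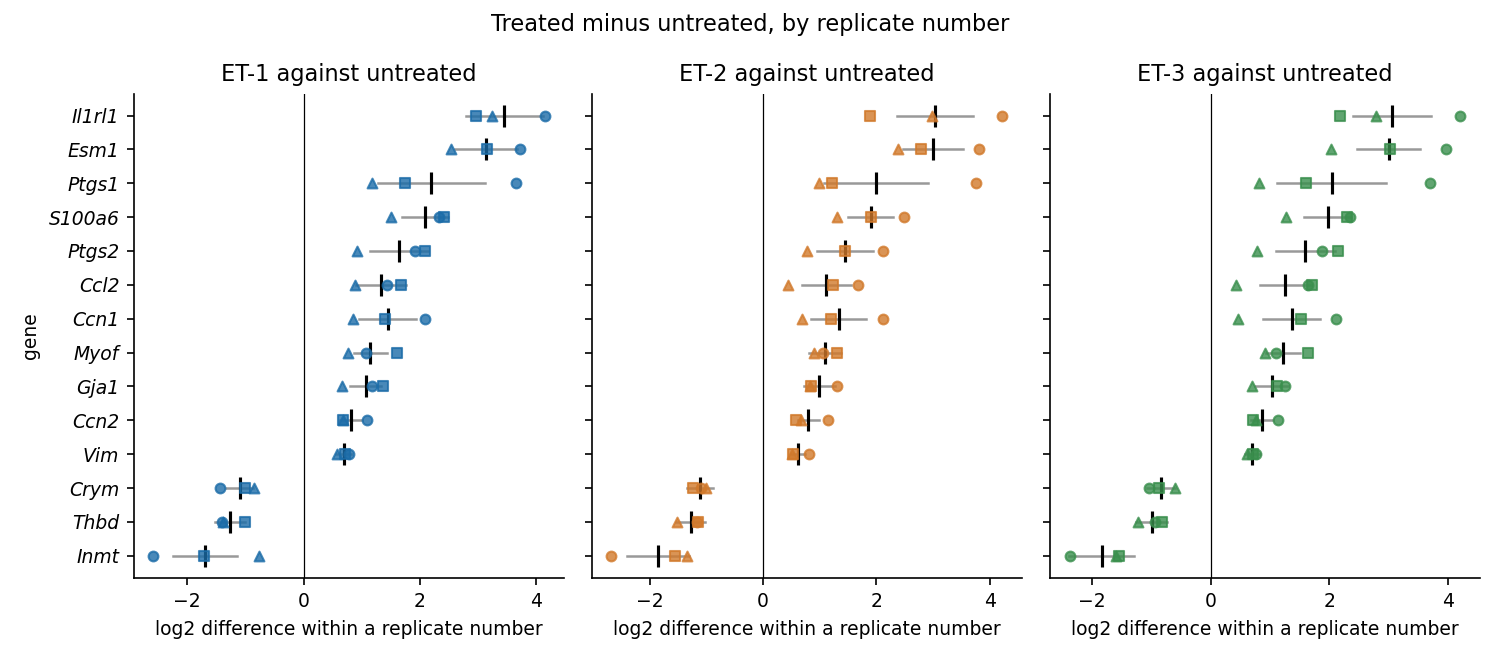
Log2 difference between each treated array and the untreated array of the same replicate number for 14 genes; circles, squares and triangles are replicates 1, 2 and 3, black ticks the mean and grey lines the 95% interval of the paired fit. Each difference has the direction of its mean, which the naming rule required of the genes it named. With ET-1 the means run from 3.45 (Il1rl1) to -1.69 (Inmt).

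ET-2 against untreated asked the same of ET-2. Il1rl1 rose by 3.04 ± 0.31 and Esm1 by 2.99 ± 0.25 on the log2 scale (SE, n = 3 pairs of arrays), followed by Ptgs1 (1.99), S100a6 (1.90 ± 0.18), Fst (1.45), Ptgs2 (1.45), Enpep, the aminopeptidase A that cleaves angiotensin II (1.35), and Ccn1 (1.33). Inmt (-1.86 ± 0.25), Thbd (-1.28 ± 0.12), Crym (-1.11 ± 0.11), the matrix genes Islr (-0.95) and Ogn (-0.94; 1 of its 3 other probe sets, at -0.81, did not pass), Cldn11 (-0.87), Kdr, the VEGF receptor of endothelium (-0.74), and Olfml3 (-0.65) fell. The adjusted p of these genes ran from 0.000373 (Esm1) to 0.0481 (Kdr) by limma in the paired fit. One direction under all 3 replicate numbers was a condition of the rule.

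Of the 36 matrix and TGF-beta target genes, 11 rose with ET-2 and 1 fell in the paired fit (18 and 1 when adjusted over the list alone). Ccn2 (0.80 ± 0.08), Timp1 (0.97), Tgfb3 (0.85), Col4a1 (0.73), Tagln (0.59) and Acta2 (0.47) were among the former, and the fibrillar collagen Col3a1 (-0.35 ± 0.07) was the latter. In the unpaired fit the list shifted upward (camera adjusted p = 2.5e-08, and 0.368 with an estimated correlation). Of 31 cell cycle genes 4 rose: Ccna2 (1.25), Ccnb2 (1.25), Mcm3 (0.82) and Ccnd1 (0.80, with 2 other probe sets at 0.50 and 1.02 that did not pass), and 16 when adjusted over the list alone (camera adjusted p = 5.9e-07; adjusted p = 0.570 with an estimated correlation). The same 4 inflammatory genes as with ET-1 rose, Ccl2 by 1.12, Ccl7 by 1.11, Icam1 by 0.69 and Ptgs2 (camera adjusted p = 0.00217; adjusted p = 0.570 with an estimated correlation), and 8 rose and 1 fell when adjusted over the list alone. None of the 18 immediate early genes passed alone, 5 did when adjusted over the list alone, and the list shifted upward (camera adjusted p = 0.000469; adjusted p = 0.368 with an estimated correlation).

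ER stress genes (Pdia6 rose by 0.28) and genes of glycolysis and hypoxia (P4ha2 rose by 0.37) also shifted upward with ET-2 (camera adjusted p = 0.0309 for both; adjusted p = 0.570 and 0.368 with an estimated correlation), though the median of the latter moved from 0.08 to -0.02 with median centring. Synaptic vesicle genes shifted downward by a median of 0.125 below 0 (camera adjusted p = 0.0309; adjusted p = 0.819 with an estimated correlation), and Bsn fell by 0.33. Plcg1, a phospholipase of calcium signalling, fell by 0.39, and the chaperone Hspa4l by 0.30. Cryab (0.93), Nqo1 (0.61), Vim (0.62 ± 0.06) and Gja1 (0.996) rose. The replicate block changed 4 list calls. Cholesterol biosynthesis (adjusted p from 0.122 to 0.00825), calcium signalling (0.0656 to 0.00967) and astrocyte and Müller glia (0.206 to 0.0167) passed with it by camera, whereas pericyte, smooth muscle and fibroblast markers (0.0499 to 0.161) passed without it. With an estimated correlation in the paired fit these 4 had an adjusted p of 0.520, 0.431, 0.417 and 0.510. The calls of the glia list and of the pericyte, smooth muscle and fibroblast list were upward, although their medians were -0.017 and -0.043. The median member of either list did not rise. None of the 24 RGC markers passed with ET-2, and their median was -0.02 (camera adjusted p = 0.828).

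The camera calls of the unpaired fit with ET-2 went from 8 lists to 0 without ET-2 replicate 1 and 5 without untreated replicate 2. These runs leave the replicate numbers unbalanced. The paired fit called 249 probe sets with ET-2, 199 higher and 50 lower (144 and 39 genes). The unpaired fit called 0 (limma; 223 had an unadjusted p under 0.05 against 776 expected, and the lowest adjusted p was 0.8544). Its rule named Myof (1.09 ± 0.18), Ccn2, Cd9 (0.62), Adamts7 (0.93), Ttc7a (0.73), Vim, Vamp5 (0.71) and Nthl1 (0.62) on the higher side and Inmt, Thbd, Cldn11 and Crym on the lower side, none past the threshold there. With each array centred on its median, the paired fit called 193 higher and 1025 lower, a centring that moved the ET-2 arrays against untreated by 0, 0.144 and 0.147 on the log2 scale in replicates 1, 2 and 3. Without single arrays the count was 27 (ET-2 replicate 1), 109 (ET-2 replicate 2), 38 (ET-2 replicate 3), 147 (untreated replicate 1) and 404 (untreated replicate 3), and without replicates 1, 2 and 3 it was 32, 44 and 143. Of the 45 named genes called here, 8 kept their call in all 12 such alternatives of the paired fit (Ccn2, Crym, Esm1, Il1rl1, Myof, S100a6, Thbd and Vim), and 37 lost it in at least 1, with an adjusted p of up to 0.378.

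ET-3 against untreated asked which genes respond to ET-3. Il1rl1 (3.06 ± 0.31) and Esm1 (3.003 ± 0.25, SE, n = 3 pairs of arrays) again had large increases, as did the chemokine Ccl20 (2.89 ± 0.62), Ptgs1 (2.04), S100a6 (1.98 ± 0.18), Hrct1 (1.73), Fst (1.68) and Ptgs2 (1.60). Inmt (-1.84 ± 0.25), Thbd (-0.999 ± 0.12), Ogn (-0.87), Crym (-0.84 ± 0.11), Agtr2 (-0.75), Islr (-0.67), Igdcc4 (-0.62) and Ano4 (-0.59) fell. The adjusted p of these genes lay between 0.000257 (Esm1) and 0.0465 (Ano4) by limma in the paired fit. Agtr2 lost its call in 7 of 12 such alternatives of the paired fit, with an adjusted p of up to 0.502 (limma, without replicate 1), while its log2 change stayed between -0.92 and -0.59.

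Inflammatory genes were the group with the most calls beyond the matrix genes. Of 27, 8 rose in the paired fit (12 when adjusted over the list alone): Ccl20, Cxcl1 (0.90), Cxcl2 (0.71), Ccl2 (1.26), Ccl7 (1.25), Icam1 (0.80), Ptgs2 and the NF-kB subunit Nfkb2 (0.85). In the unpaired fit the list shifted upward (camera adjusted p = 2.1e-05, and 0.429 with an estimated correlation). Among 36 matrix and TGF-beta genes 14 rose (19 rose and 1 fell when adjusted over the list alone), including Ccn1 (1.36), Ccn2 (0.87 ± 0.08), Tgfb3 (1.09), Timp1 (1.002), Fbln2 (0.94), Col4a1 (0.88), Tagln (0.82) and Acta2 (0.63) (camera adjusted p = 1.6e-09; adjusted p = 0.232 with an estimated correlation). Kif20a (1.52), Ccna2 (1.25) and Mki67 (1.06) rose among 31 cell cycle genes, 19 when adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.524 with an estimated correlation). Egr1 (0.72) and Ier3 (0.77) rose among immediate early genes, 7 when adjusted over the list alone (camera adjusted p = 0.000152; adjusted p = 0.232 with an estimated correlation).

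ER stress genes (Pdia6 0.29, Calr 0.33, Creld2 0.52, all higher) and cholesterol biosynthesis genes (Msmo1 rose by 0.53) shifted upward with ET-3 (camera adjusted p = 0.0299 and 0.0368; adjusted p = 0.524 and 0.708 with an estimated correlation). Cryab (1.14), Hspb1 (0.92), Nqo1 (0.70) and Adm (0.82) rose. Synaptic vesicle genes (median -0.11), voltage-gated channels (-0.14) and calcium signalling genes (-0.09) shifted downward (camera adjusted p = 0.00935, 0.0177 and 0.00968; adjusted p = 0.560, 0.524 and 0.429 with an estimated correlation). Bsn (-0.35), Kcna2 (-0.36) and Scn3b (-0.26) fell, as did Ret, a receptor of GDNF family ligands (-0.33; 2 other probe sets at -0.24 and -0.09 did not pass). Of 21 apoptosis genes, Bcl2l11 (-0.31) and Gadd45a (-0.26) fell and Gadd45b (0.42) rose. Vim (0.70 ± 0.06), Gja1 (1.03) and Clu (0.33) rose among 8 glial markers, and Pdgfrb (1.09 ± 0.24), Acta2 and Tagln among 9 pericyte, smooth muscle and fibroblast markers. No RGC marker passed, and their median was -0.05 (camera adjusted p = 0.282). The replicate block gave a call to glia (0.0514 to 0.00225), axonal transport (0.159 to 0.0174) and glycolysis and hypoxia (0.0526 to 0.0306) by camera and ended that of the pericyte, smooth muscle and fibroblast list (0.0279 to 0.0936), whose median of 0.04 moved to -0.01 with median centring. In the paired fit with an estimated correlation these 4 had an adjusted p of 0.187, 0.272, 0.272 and 0.329.

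The camera calls of the unpaired fit with ET-3 went from 10 lists to 1 without ET-3 replicate 1, a run that leaves the replicate numbers unbalanced. The paired fit called 410 probe sets with ET-3, 331 higher and 79 lower (253 and 54 genes). The unpaired fit called 0 (limma; 297 had an unadjusted p under 0.05 against 776 expected, and the lowest adjusted p was 0.6088). Its rule named Myof (1.22 ± 0.18), Ccn2, Vamp5 (0.89), S100a4 (1.24), C1h19orf33 (1.33), Adamts7 (1.03), Cd9 (0.68) and Vim on the higher side and Inmt, Thbd, Igdcc4, Cldn11 (-0.69), Gstt3 (-0.68), Gria4 (-1.08) and Plvap (-0.70) on the lower side, none past the threshold there. Cldn11, Gstt3, Gria4 and Plvap missed it in the paired fit too. Median centring gave 228 higher and 218 lower in the paired fit. Without single arrays the count was 86 (ET-3 replicate 1), 97 (ET-3 replicate 2), 245 (untreated replicate 1) and 685 (untreated replicate 3), and without replicates 1 and 2 it was 90 and 43. Of the 60 named genes called here, 12 kept their call in all 12 such alternatives of the paired fit, among them Acta2, Cryab, S100a4 and Tgfb3, and 48 lost it in at least 1, with an adjusted p of up to 0.502.

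The mean of the 3 endothelins against untreated asked for the response common to the peptides, with 9 treated arrays. Il1rl1 (3.18 ± 0.25), Esm1 (3.04 ± 0.20), Ccl20 (2.55 ± 0.51), Ptgs1 (2.08 ± 0.35), the cytokine Il6 (2.02 ± 0.46) and S100a6 (1.99 ± 0.15) rose most on the log2 scale. Inmt (-1.80 ± 0.21), Thbd (-1.18 ± 0.10), Crym (-1.02 ± 0.09), Angpt2, an angiopoietin of vessels (-0.92 ± 0.20), Ogn (-0.88 ± 0.11) and Cldn11 (-0.88 ± 0.15) fell. Their adjusted p ran from 2.8e-05 to 0.0249 by limma in the paired fit. Of 31 cell cycle genes 14 rose (20 when adjusted over the list alone), of 36 matrix genes 16 rose and 1 fell (23 and 1), of 27 inflammatory genes 9 rose (13), and of 18 immediate early genes 5 rose (7). These 4 lists shifted upward (camera adjusted p = 3.1e-08, 7.7e-11, 2.2e-05 and 2.2e-05; adjusted p = 0.462, 0.226, 0.446 and 0.224 with an estimated correlation). The replicate block gave a call to glia (0.0686 to 0.00594) and axonal transport (0.235 to 0.0470) by camera and ended that of the pericyte, smooth muscle and fibroblast list (0.0164 to 0.0549). With an estimated correlation in the paired fit their adjusted p by camera was 0.262, 0.287 and 0.287. The glia median of 0.055 moved to -0.002 with median centring.

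None of the 5 fibroblast markers measured in the pericyte, smooth muscle and fibroblast list was called higher for the mean, a subset formed after the results were seen. With the mean of the 3 endothelins Col1a1 was at 0.02 ± 0.11, Col1a2 at 0.12 ± 0.11, Lum at -0.09 ± 0.14 and Dcn at -0.27 ± 0.17, none past the threshold, and Col3a1 fell by 0.27 ± 0.05 (adjusted p = 0.0144 by limma in the paired fit). Of the pericyte and smooth muscle genes of the same list, Pdgfrb rose by 1.02 ± 0.19, Tagln by 0.72 ± 0.09 and Acta2 by 0.55 ± 0.06, while Myh11 was at 0.14 ± 0.10 and did not pass. The difference between these subsets was not tested. Among 24 RGC markers 1 fell. Thy1, the panning antigen, was at 0.00 ± 0.08, Sncg at 0.07 ± 0.07 and Rbpms at -0.07 ± 0.05, with no call and with a sign that turned under quantile normalization for Thy1, Sncg and Col1a1 and under median centring for Thy1 and Col1a1. In the endothelin system, Ece1 was at 0.17 ± 0.07, Ece2 at -0.07 ± 0.14 and Ecel1 at -0.13 ± 0.06, none past the threshold; Edn1 and Edn2 lay below the signal filter, and Edn3, Ednra and Ednrb were not analysed here. The lists for MAPK feedback, apoptosis, neurotrophic factors, oxidative phosphorylation, oxidative stress, axon injury, glutamate receptors, microglia, amacrine cells and horizontal cells did not pass by camera in either fit against untreated, with medians between -0.16 and 0.03 for the mean of the 3.

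The paired fit called 758 probe sets for the mean of the 3, 549 higher and 209 lower (412 and 153 genes). The unpaired fit called 0 (limma; 397 had an unadjusted p under 0.05 against 776 expected, and the lowest adjusted p was 0.1279). Its rule named Myof (1.15 ± 0.15), Ccn2, Cd9 (0.66), Vamp5 (0.80), Vim, Tnfaip2 (0.77), Inmt, Thbd and Cldn11. Median centring gave 426 higher and 1066 lower in the paired fit, and the count was 226 without replicate 1, 224 without replicate 2, 334 without untreated replicate 1 and 484 without ET-2 replicate 1. Of the 22 named genes called here, 15 kept their call in all 18 such alternatives of the paired fit. Ccl20, Il6, Cd9, Angpt2, Cldn11, Col3a1 and Pdgfrb lost it in at least 1, with an adjusted p of up to 0.241 (Angpt2 without replicate 1), and without replicate 2 that of Il6 was 0.114 and that of Ccl20 0.156 (limma). Over the alternatives the log2 change ran from 0.933 to 2.747 for Il6 and from 1.635 to 3.673 for Ccl20.

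**Figure D4:**
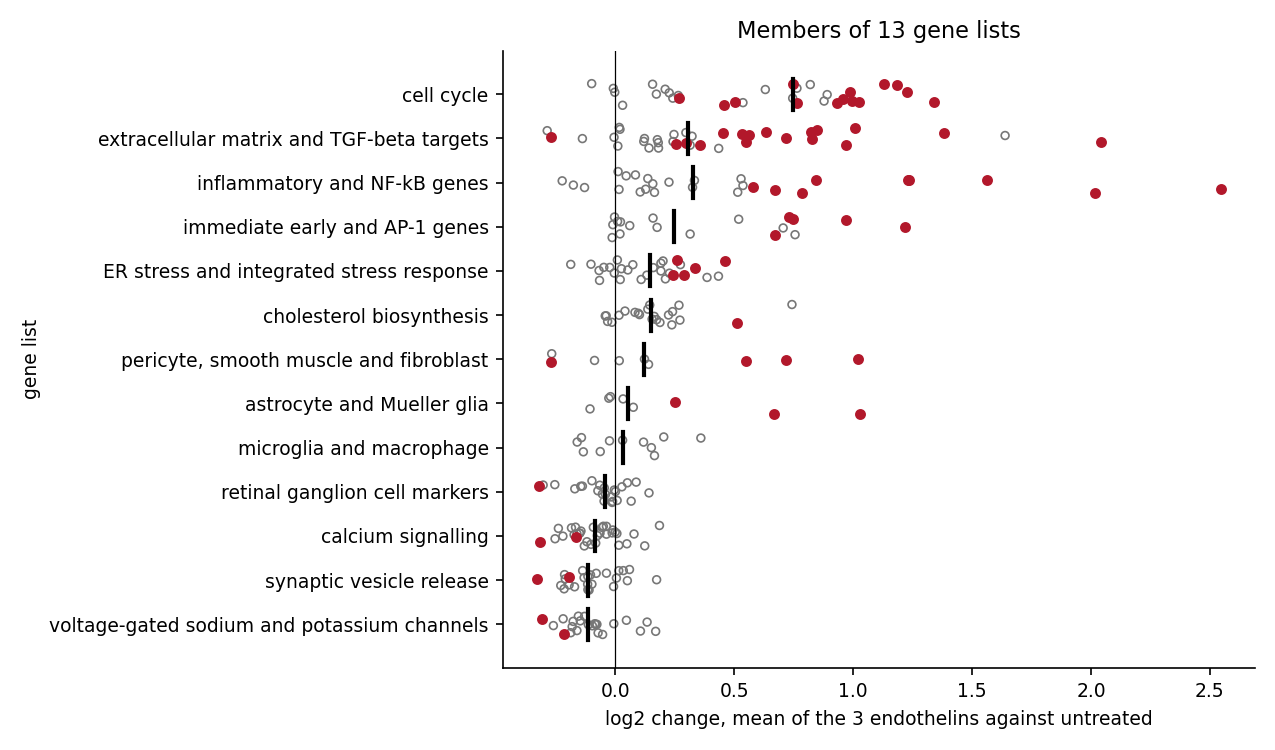
Log2 change of the measured members of 13 gene lists for the mean of the 3 endothelins against untreated; filled points passed the paired fit, open points did not, and black bars are list medians. Cell cycle genes have a median of 0.75, whereas RGC markers lie around -0.04.

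The peptides were then compared directly, to ask whether ET-1, ET-2 and ET-3 differ at one dose and time. No probe set differed between ET-2 and ET-1, ET-3 and ET-1, or ET-3 and ET-2 in either fit (limma). In the paired fit 574, 347 and 583 probe sets had an unadjusted p under 0.05, and in the unpaired fit 41, 23 and 46, against 776 expected. The rule named Wiz (0.85) and Fah (0.60), higher with ET-2 than with ET-1, and Caskin1 (-0.65); Wiz (0.69) for ET-3 against ET-1; and C1h19orf33 (0.60), Cdh6 (-0.69) and Gatad2b (-0.80) for ET-3 against ET-2. None passed, with an adjusted p of 0.9989 or more in the paired fit. Among the 503 probe sets called with at least 1 peptide, none had fold changes of opposite sign, which the shared untreated arrays favour even without an effect, and the median absolute difference between peptides was 0.085 to 0.115 against a median 95% half-width of 0.248. In the self-test the paired fit recovered 36 to 40% of changes of 0.5 for single peptides, each against untreated; direct peptide contrasts were not simulated, and the peptides are not shown to act alike.

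Log2 changes of the peptides correlated across probe sets, with r = 0.823 for ET-1 and ET-2, 0.869 for ET-1 and ET-3, and 0.827 for ET-2 and ET-3; probe sets are not independent replicates. Simulations without any effect against the same untreated arrays gave a mean r of about 0.50 and at most 0.534 with the paired spread. The covariances were 0.0409, 0.0458 and 0.0421, beside simulated means of 0.00962, 0.00960 and 0.00963. With the unpaired spread the simulated means were 0.0565, above the observed values. The latter simulations took the variance between replicate numbers as separate for each array, which the data contradict, so they cannot be compared with these values. Called higher probe sets overlapped by 148, 204 and 172, against 3, 4.99 and 4.24 for independent lists, and lower ones by 15, 18 and 19, against 0.11, 0.17 and 0.25. Il1rl1, Esm1, S100a6 and Vim were among the 140 called higher with all 3 peptides, and Inmt, Thbd and Crym among the 12 called lower. The untreated arrays are shared and too few to split, so part of this overlap may come from them.

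**Figure D5:**
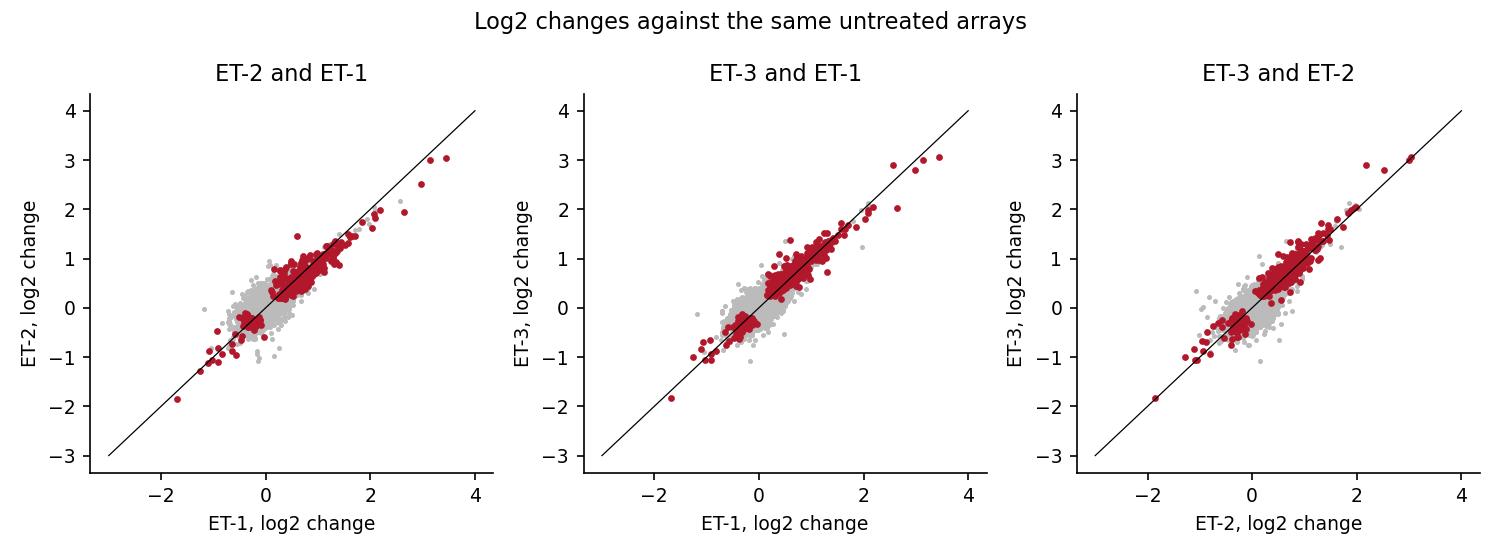
Log2 change with one peptide against that with another over 15521 probe sets, all against the same untreated arrays; red points passed the paired fit with at least 1 of both peptides, and the line marks equal change. Points lie along the line, with r from 0.823 to 0.869.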

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

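The tests of the change in pericyte, smooth muscle and fibroblast markers, of the marker profile in the untreated arrays and of the shared untreated arrays were chosen after the results were seen; the other tests of this part were set before.

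In the direct comparisons of peptides, 7 shifts of gene lists passed by camera in the paired fit, although no single probe set did. With ET-2 rather than ET-1, 4 lists lay lower: cholesterol biosynthesis (median log2 difference -0.087, adjusted p = 0.00543), microglia and macrophage (-0.164, 0.00549), matrix and TGF-beta targets (-0.105, 0.0224) and inflammatory genes (-0.160, 0.0281). RGC markers lay higher there (0.051, 0.0402). With ET-3 rather than ET-2, inflammatory genes (0.171, adjusted p = 0.000872 by camera) and microglia and macrophage markers (0.178, 0.00736) lay higher. None passed in the unpaired fit (adjusted p from 0.512 to 0.596) or in the paired fit with an estimated correlation (0.704 to 0.934).

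The first pattern weighed is the set of genes called higher with endothelin in the paired fit, among them genes of the matrix, inflammatory and cell cycle lists; none of these lists passed by camera with an estimated correlation. More fibroblasts in the treated dishes would raise fibroblast markers alike. The 5 measured in the list (Col1a1, Col1a2, Col3a1, Dcn and Lum) had a median log2 change of -0.087 (SD 0.173), against 0.575 for the genes called higher. The genes called higher were picked by these same arrays, which raises their median. The values argue against a gain of fibroblasts as large as that rise, not against a smaller one. They do so only if endothelin left these markers unchanged within fibroblasts, which was not tested. The authors' scaling as the source of this number is argued against by 476 probe sets called higher after quantile normalization, beside 549. How many of the 476 are among the 549 was not counted. Of 376 genes called higher by their representative probe set, markers left out, 76.3% followed the marker profile over the 3 replicate numbers (r over 0.5). That share includes treated arrays, and random lists had a median of 30.9%, with 1 in 40 above 35.1%. In the 3 untreated arrays alone it was 62.2% (random lists: median 33.8%, with 1 in 40 above 38.3%), and 1 of 24 RGC markers passed. The markers were highest in replicate 1, so any difference that raises genes there would also pass. Random lists held genes drawn separately, which leaves out genes that vary together. The shares therefore cannot tell which cells responded. A response of non-neuronal cells, which panning with Thy-1.1 antibody is meant to remove, stays open. More pericytes or smooth muscle cells cannot be told apart from their response to endothelin: 4 markers had a median of 0.634 (SD 0.368), and Acta2 and Tagln of that list are also members of the matrix list.

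The next pattern is that arrays with one replicate number stand together. The distribution of signal is argued against, since quantile normalization left 98.1% of the variance of the first component between numbers. The cell make-up of the cultures may contribute: mean log2 levels of pericyte, smooth muscle and fibroblast markers spanned 1.528 between numbers, above 0.482 for random lists, and RGC markers spanned 0.545 the other way. Some pathway lists also passed the limit of their random lists, such as cholesterol biosynthesis (0.849 against 0.296) and oxidative stress (0.572 against 0.284). Others, such as apoptosis (0.099 against 0.294), did not. A wide span is therefore not particular to cell type markers. Other differences between replicate numbers were not tested and stay open.

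The last pattern is the alike fold changes of the peptides. The lowest covariance was 0.0409, above the highest of 0.0108 in simulations without effect and with the paired spread. It lay below the simulated means of 0.0565 with the unpaired spread. That spread holds the variance between replicate numbers, which was drawn for each array on its own. In the data, arrays of the same number deviated together (r from 0.684 to 0.912), so those means cannot be compared with the observed value. The simulations drew noise for each probe set on its own, so they leave out shifts that many probe sets share on an untreated array. They therefore cannot decide whether the shared untreated arrays alone give this pattern. Part of the covariance may come from those arrays. For the mean of the 3, the paired fit called 758 probe sets with the real untreated arrays. Among 64 choices of 1 array per replicate number, the highest other called 1. For the called probe sets these counts argue against noise of the untreated arrays alone, without excluding it. A common response to the 3 peptides was not tested apart from those arrays and stays a hypothesis.

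Other splits of the arrays were counted. For each of the 6 comparisons of 3 with 3 arrays in the unpaired fit (limma), all 10 of 10 splits gave as many probe sets, with a real count of 0 and a highest other count of 0, and 10 splits are too few for a share under 0.05. Swaps of treated and untreated within replicate numbers in the paired fit gave as many in 1 of 4 for ET-1 (268), ET-2 (249) and ET-3 (410), with a highest other count of 0, and 4 are again too few. For the mean of the 3, 100 of 100 splits gave at least the real 0 in the unpaired fit, as they must, so this says nothing about chance. The split that set the 3 treated arrays of replicate 1 against the rest called 3622, which points to a structure of the samples; that of replicate 2 called 5, and 4 other splits within 1 replicate number called 0. In the paired fit 1 of 64 choices, the real one with 758, called as many, and the highest other called 1. This is the lowest share that 64 choices can give, so it speaks against chance but does not exclude it. The other choices mix real untreated and treated arrays, which raises their spread where a difference exists.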

How the results depend on the processing

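Repeats inside the paired fit, the random block, whole replicates left out and the paired list test with an estimated correlation were chosen after the data were seen.

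With the replicate block limma called 268, 249 and 410 probe sets for ET-1, ET-2 and ET-3 and 758 for their mean, where the unpaired fit called 0 (unadjusted p under 0.05: 237, 223, 297 and 397). The unpaired fit also called 0 under every other alternative run, except 2 for the mean with array weights. The block removes the variance between replicate numbers.

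In the paired fit ET-1 gave 123 without trend, 78 with only the 2 groups and 94 with a random block, and 23 to 575 with arrays or replicates left out. ET-2 gave 1218 with median centring, 135 without filter, 159 with the 75th percentile filter, 71 without trend, 56 with the 2 groups, 23 with a random block and 27 to 404 with arrays left out. ET-3 gave 273 without filter, 170 without trend, 211 with array weights, 56 with the 2 groups, 117 with a random block and 43 to 685. The mean gave 1492 with centring, 438 without trend, 332 with array weights, 337 with a random block and 224 to 1014. ET-2 against ET-1 ran from 0 to 1, and the other peptide contrasts stayed at 0 (limma; unadjusted p under 0.05: 347 and 583). The cause was not tested.

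List counts (11, 8 and 10) became 14, 10 and 12 with the block and 0, 0 and 0 with an estimated correlation, paired or not. ET-2 gave 3 without filter and 5 with the mean of a gene's probe sets, and ET-3 gave 5 without filter. Arrays left out, in the unpaired fit, gave 3 to 13, 0 to 11 and 1 to 13 lists. The lowest count came each time without the treated array of replicate 1. Inflammatory, matrix and cell cycle genes were highest in replicate 1, and leaving out 1 array unbalances the replicate numbers. That imbalance alone can move these counts. No list test with a whole replicate left out was run. Correlations between peptides fell to 0.568, 0.562 and 0.603 without filter, which adds probe sets of low signal (the cause was not tested). With 1 untreated array left out in the unpaired fit they ran from 0.833 to 0.898, 0.876 to 0.923 and 0.838 to 0.897. Leaving out an untreated array adds the same replicate difference to the changes of all 3 peptides, which favours a higher r. These ranges therefore do not show how stable the correlations are.

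Unpaired log2 changes that turned sign with an array left out ran, for ET-1, from -1.515 to 0.063 (Ogn) and -0.126 to 0.609 (Clu); for ET-2, from -1.151 to 0.430 (Col3a1) and -1.194 to 0.035 (Olfml3); for ET-3, from -0.037 to 0.707 (Clu), -1.573 to 0.016 (Ogn), -1.292 to 0.090 (Islr), -2.672 to 1.264 (Agtr2) and -0.072 to 0.789 (Calr). For the mean they ran from -1.389 to 0.009 (Ogn), -0.557 to 0.908 (Col1a1), -0.401 to 0.948 (Col1a2), -1.016 to 0.490 (Col3a1), -0.761 to 0.561 (Dcn), -0.602 to 0.739 (Lum), -0.229 to 0.407 (Myh11), -0.157 to 0.231 (Sncg), -0.319 to 0.248 (Thy1), -0.223 to 0.096 (Rbpms) and -0.168 to 0.068 (Ece2). Leaving out an array unbalances the replicate numbers. Quantile normalization gave -0.001 (Col1a1), -0.050 (Sncg) and -0.009 (Thy1) and median centring -0.039 (Col1a1) and -0.056 (Thy1); the cause was not tested. In the paired fit no named gene that was called changed sign with arrays or replicates left out, another scaling or a pseudocount. For many of these genes the naming rule had required one direction under all 3 replicate numbers, which favours this.

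The signal filter left probe sets below about 147.5, Edn1 and Edn2 among them, without a test.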

Other observations

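The values of this part were chosen after the results were seen. The measured change differed in size between replicate numbers. For the mean of the 3 endothelins, the median log2 change of the 549 probe sets called higher was 0.705 in replicate 1, 0.535 in replicate 2 and 0.372 in replicate 3, and that of the 209 called lower -0.303, -0.266 and -0.222. These probe sets were chosen by the same arrays, and the order of the numbers carries no meaning. The SD of this change over all tested probe sets was 0.354, 0.269 and 0.216 in replicates 1, 2 and 3. It fell in the same order. Whether the response or the general spread of the changes differed was not tested.

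Levels also differed in other lists. Mean log2 levels in replicates 1, 2 and 3 were 10.33, 9.06 and 9.17 for inflammatory genes, 11.07, 10.38 and 9.85 for matrix genes, 9.45, 8.26 and 8.25 for cell cycle genes, and 8.60, 9.28 and 8.58 for microglia and macrophage markers. Untreated signals of Il1rl1 were 656, 246 and 199, and those of Ptgs2 878, 287 and 333.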
